A study of Canis lupus familiaris with 6 samples.

How the data were processed

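Gene expression was measured in cylindrical bone specimens of 4.5 mm diameter and 8 mm length from the mandible of beagle dogs aged 9 years. Per the labels' protocols, holes were drilled after 3 months of healing from premolar extraction and left without beta-TCP (control) or implanted with it (beta-tricalcium phosphate, a resorbable ceramic bone substitute). Specimens were taken 4, 7 and 14 days later, and labelled RNA was prepared from 100 ng of total RNA for an Affymetrix canine array. There are 6 arrays in 6 groups, 1 array per group. The number of animals, and which specimens shared an animal, are not given in the sources used here.

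The deposited table holds 42860 probe sets on all 6 arrays, without control probe sets or detection calls. For days 4 and 7, the values the authors deposited are a signal divided by the array's own median (medians 1.00), with the lowest values set to 0.01. For day 14, the deposited values are an undivided intensity, with a median of 12.0 on the control array and 6.2 on the beta-TCP array. The units were read from the values. The software, algorithm and scaling that made them are not given in the sources used here.

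Every array was divided by its own median over the 42860 probe sets, and log2(value + 1) was taken. On this scale differences of weakly expressed genes are understated. A table of probe sets and genes gave 1 gene for 29254 probe sets, several genes for 439 and no gene for 13167. By gene ID, 27680 of the 29254 matched the RefSeq gene table of the assembly UU_Cfam_GSD_1.0, used for names only. The probe set with the highest mean stood for each of 15156 genes, and the 10550 genes whose mean reached the 40th percentile of the means of all probe sets (those in the pairs left out not counted) were kept.

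Several of these choices were made after the values had been seen, and depart from the design fixed before the data were examined. That design took the values as deposited with a pseudocount of 16. Division by the array median and a pseudocount of 1, both listed beforehand as options to try, became the main setting because of the different scales. A pseudocount of 16 lies near the 90th percentile of the divided values. Also left out were 90 pairs of probe sets (180 probe sets) that share a name stem and end in _a_at and _at, because the 19 of these pairs that lay over 2 log2 units apart run the other way round at day 14 than at days 4 and 7. For the other pairs the order was not assessed.

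With 1 array per group, beta-TCP minus control on each day and the differences between days within a treatment (9 comparisons) have no replicate check and no test. They are given as log2 differences and as counts of genes that differed at least 2-fold. A list of genes was described by its median log2 difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Lists below 2.5 or above 97.5 are called outside the band. The percentile describes these arrays and is not a p-value. It treats genes as independent, so co-regulated lists leave the band more often than independent ones would.

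The average effect of beta-TCP over the 3 days was tested with limma's moderated test in an additive fit of day and treatment to all 6 arrays (2 residual degrees of freedom, two-sided, Benjamini-Hochberg adjusted p under 0.05). Differences in the treatment effect between days, between specimens or animals, and between arrays all enter the residual of that fit, so its p-values measure only that mixture. An F test over the day coefficients and contrasts between days came from the same fit. Lists of at least 5 kept genes were tested in it with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry.

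The 30 gene lists, covering bone, matrix, immune, vascular, other tissue and housekeeping genes, and the rule for named genes were fixed before the data were examined. The rule names the 10 highest and 10 lowest genes on each day, the 10 highest and 10 lowest of the additive fit (with no gene past the threshold, those with the smallest p and the same sign on all 3 days), and the 10 highest and 10 lowest between days 14 and 4 that changed at least 2-fold in both treatments. It adds the leading members of the lists and a fixed set of bone, osteoclast, macrophage and cartilage markers. Genes named only by an identifier were passed over.

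The fit was tested on simulated data with the real means and day effects of the 10550 genes. Their variances were drawn from the distribution that the fit estimated from the real residuals. Noise was independent, and each changed gene changed by the same amount on all 3 days. Of 50 genes changed by 1, 2, 3 and 4 log2 units in beta-TCP minus control, the fit called 4%, 70%, 100% and 100%. There were 3 false calls. These shares do not cover genes whose difference varied between days. The percentile was tested in 50 draws of independent noise at each shift. A list of 22 genes left the band upwards in 0, 21, 46 and 50 draws when shifted by 0, 0.25, 0.5 and 1 log2 units, and an unshifted list of 29 genes did so in 0 to 3. This test was recast over repeated draws after a single draw at a shift of 0.5 had stayed inside the band.

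Alternatives covered the scaling, the pseudocount, the expression filter, the choice of probe set, the fold and p thresholds, the form of the fit and each day's pair of arrays left out. R 4.3.3, limma 3.58.1, matrixStats 1.5.0, Python 3.11.15 and matplotlib 3.10.9 were used. The number of arrays limits the precision of every value.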

Results

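Transcript levels were compared between drilled mandibular bone sites of beagle dogs without beta-TCP (control) and sites implanted with it, at 4, 7 and 14 days. Each of the 6 groups holds 1 array, so differences on a single day carry no error and no p-value. Differences are on the log2 scale, beta-TCP minus control unless stated otherwise, from values divided by the array median.

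The 6 arrays did not stand equally close to one another. The array labelled beta-TCP day 14 had Spearman correlations of 0.723 to 0.779 with the others, against 0.832 to 0.905 among the other 5. On it, 241 probe sets lay at least 4-fold below every other array, against 0 to 12 on the others. For 1638 genes with a mean log2 of at least 2 on probe sets of both name types, Cfa and CfaAffx, the centred difference CfaAffx minus Cfa had a median of 0.36 and 0.38 at day 4 (control, beta-TCP). It was 0.03 and 0.20 at day 7, and -0.17 and -0.77 at day 14.

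**Figure D1:**
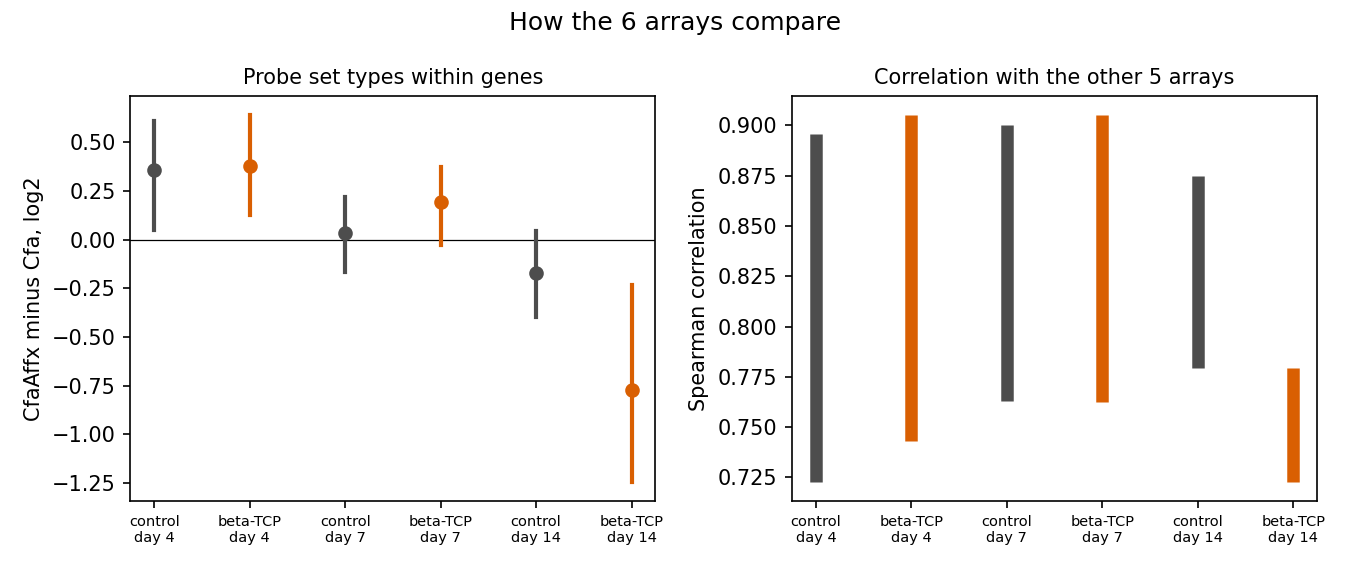
Left, the median (point) and the interquartile range (line) over 1638 genes of the log2 difference between CfaAffx and Cfa probe sets of a gene, centred over the arrays, for each array. Right, the range of each array's Spearman correlations with the other 5 arrays; the beta-TCP day 14 array reaches at most 0.779.

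The first question was how the implanted site differed from the control site early in healing. At day 4, the highest genes with beta-TCP included asporin (ASPN, 2.52), bone sialoprotein (IBSP, between ASPN and OMD), osteomodulin (OMD, 2.45), periostin (POSTN, 2.42) and tenascin N (TNN, 2.24). The growth factor pleiotrophin (PTN) differed by 2.30, and LPL, C1S, RARRES1 and VCAM1 by 2.27 to 2.39. Among the lowest were genes known from stratified epithelium, KRTDAP (-3.82), LAMA3 (-3.67), S100A14 (-3.66), S100A2 (-3.13) and DSC2 (-2.86), together with SERPINB2 (-4.18), SLC6A14 (-3.14) and S100A5 (-2.97). The cytokine gene IL1B (-2.89) and the immediate early gene NR4A1 (-2.82) were also among them. Of 3 probe sets of LAMA3 above the filter, 1 had the opposite sign (0.84), and of 4 of C1S the lowest lay at 0.016. Over the genes named as highest or lowest on a day, 26 entries had several probe sets above the filter, and in 13 of them at least 1 other probe set gave under 50% of the value printed.

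The lists fixed for granulation tissue and for inflammatory cytokines and neutrophils lay on opposite sides at day 4. The fibrous matrix and granulation tissue list had a median of 0.91 (percentile 100), with 10 of 23 genes at least 2-fold higher and 0 lower, among them COL6A1 (1.65), PDGFRB and decorin (DCN, 1.41). At day 14 the same list lay at -0.37, inside the band (percentile 46.7), with 0 genes at least 2-fold higher and 10 lower. The osteoblast and bone matrix list lay inside the band at day 4 (0.29, percentile 77.4). The cell cycle list lay at 0.77 (percentile 100), with 26 of 29 genes higher but only 1 of them at least 2-fold. Endothelial genes had a median of 0.55 (percentile 99.9), led by ANGPT2 (1.59) and the VEGF receptor gene KDR (1.55). Inflammatory cytokines and chemokines had a median of -0.58 (percentile 0), with 9 of 24 genes at least 2-fold lower and 2 higher. The lower ones included PTGS2 (-2.59), CCL4 (-2.25) and CCL3 (-2.24). The neutrophil list lay at -0.84, the immediate early and stress list at -0.70, and the hypoxia and glycolysis list at -0.48, each at percentile 0. Epithelial markers, a cell type other than bone, had a median of -1.22 on the same day (percentile 0).

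In all, 476 genes were at least 2-fold higher and 326 lower at day 4, of 10550. The median of all genes lay at 0.17, and relative to it 241 were higher and 532 lower. With quantile normalization the split was 303 and 485, so the excess of higher genes comes with the scaling.

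At day 7, neuropeptide Y (NPY) differed by 4.92, the phosphodiesterase gene ENPP6 by 4.08, the microfibril gene MFAP5 by 3.71, POSTN by 3.44 and N-cadherin (CDH2) by 3.12. FABP4, GPRC5C, TNN, PTN and NDNF were between 3.10 and 3.38. The osteoblast and bone matrix list had a median of 0.62 (percentile 100), with 8 of 22 genes at least 2-fold higher and 1 lower. Its largest members were the osteocyte gene MEPE (3.02), the parathyroid hormone receptor gene PTH1R (2.56), IBSP (2.16) and PHEX (2.04). The cartilage list had a median of 1.03 (percentile 100), with aggrecan (ACAN) at 2.23 and CNMD at 1.83, and 2 of its 9 genes at least 2-fold lower.

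Genes of osteoclasts, lysosomes and hypoxia were lower at day 7. The osteoclast list had a median of -0.80 (percentile 0.01), with 12 of 13 genes lower, among them MMP9 (-1.66), the proton pump gene TCIRG1 (-1.21) and the tartrate-resistant acid phosphatase gene ACP5 (-1.10). Lysosome and phagosome genes lay at -0.74 (percentile 0). Hypoxia and glycolysis genes also lay at -0.74 (percentile 0), with 10 of 26 at least 2-fold lower, such as the glucose transporter gene SLC2A1 (-2.38), VEGFA (-1.57) and PGK1 (-1.46). The neutrophil list had a median of -0.65 and the inflammatory list of -0.49. The lowest single genes were CD5L (-3.01), CXCL13 (-2.91), SLC13A2 (-2.42) and CRYAB (-2.41), followed by PKIA, PLA2G15, VASP, ITGB7 and MMP3 between -2.33 and -2.18. Counted over all genes, 312 were at least 2-fold higher and 362 lower. Relative to the median of all genes (-0.085) the split was 374 and 278, and with quantile normalization 315 and 290, so the direction of the majority turns with the scaling. It also turns with the type of probe set, with 2.95% higher and 3.79% lower on Cfa probe sets alone against 2.84% and 2.52% on CfaAffx.

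At day 14, NPY (5.68), ENPP6 (3.66), SAMD11 (3.48), MEPE (between DPP4 and PHEX) and PHEX (2.41) were among the highest. DPP4, CP, CRYM and FBXO39 lay between 2.42 and 2.61. Osteoblast and bone matrix genes had a median of 0.32 (percentile 99.9), with 5 of 22 at least 2-fold higher, among them osteocalcin (BGLAP, 1.72), and 2 lower, FKBP10 (-3.31) and MSX2 (-1.51). The osteoclast list had a median of 0.51 (percentile 99.9), with ACP5 at 2.12, MMP9 at 1.41 and ATP6V0D2 at 1.40. With CfaAffx probe sets alone that percentile was 49.96, and ACP5 had a difference of -0.84. MSN was named at 3.18, but 2 of its 3 probe sets had the opposite sign, down to -1.72.

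Most genes that differed at day 14 were lower with beta-TCP, on the array that stood apart and had the lowest CfaAffx minus Cfa median. The lowest were the class I histocompatibility gene DLA88 (-8.43), CXCL8 (-4.56), the immunoproteasome gene PSMB9 (-4.38), the collagen chaperone gene SERPINH1 (-4.06), osteoglycin (OGN, -3.87) and SRGN (-3.86). The other probe set of DLA88 lay at -3.37. SORL1, PDK4, MX1 and MARCO lay between -3.60 and -3.39. Secretory pathway genes had a median of -1.01 (percentile 0.01), cell cycle genes of -0.99 (percentile 0), inflammatory genes of -1.02 (percentile 0.01) and antigen presentation and interferon genes of -0.86 (percentile 0.38). With CfaAffx probe sets alone the inflammatory list lay at percentile 63.85. The neutrophil list (-0.44, percentile 21.3, 5 higher and 6 lower) and the hypoxia and glycolysis list (-0.49, percentile 15.5) lay inside the band. Common reference genes, included as a background, had a median of -0.77 (percentile 3.45).

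At day 14, 367 genes were at least 2-fold higher and 1627 lower. The median of all genes lay at -0.23, and relative to it 716 were higher and 996 lower. The split was 775 and 1081 with quantile normalization and 968 and 848 with arrays scaled to the 90th percentile, so the direction of the majority turns with the scaling.

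**Figure D2:**
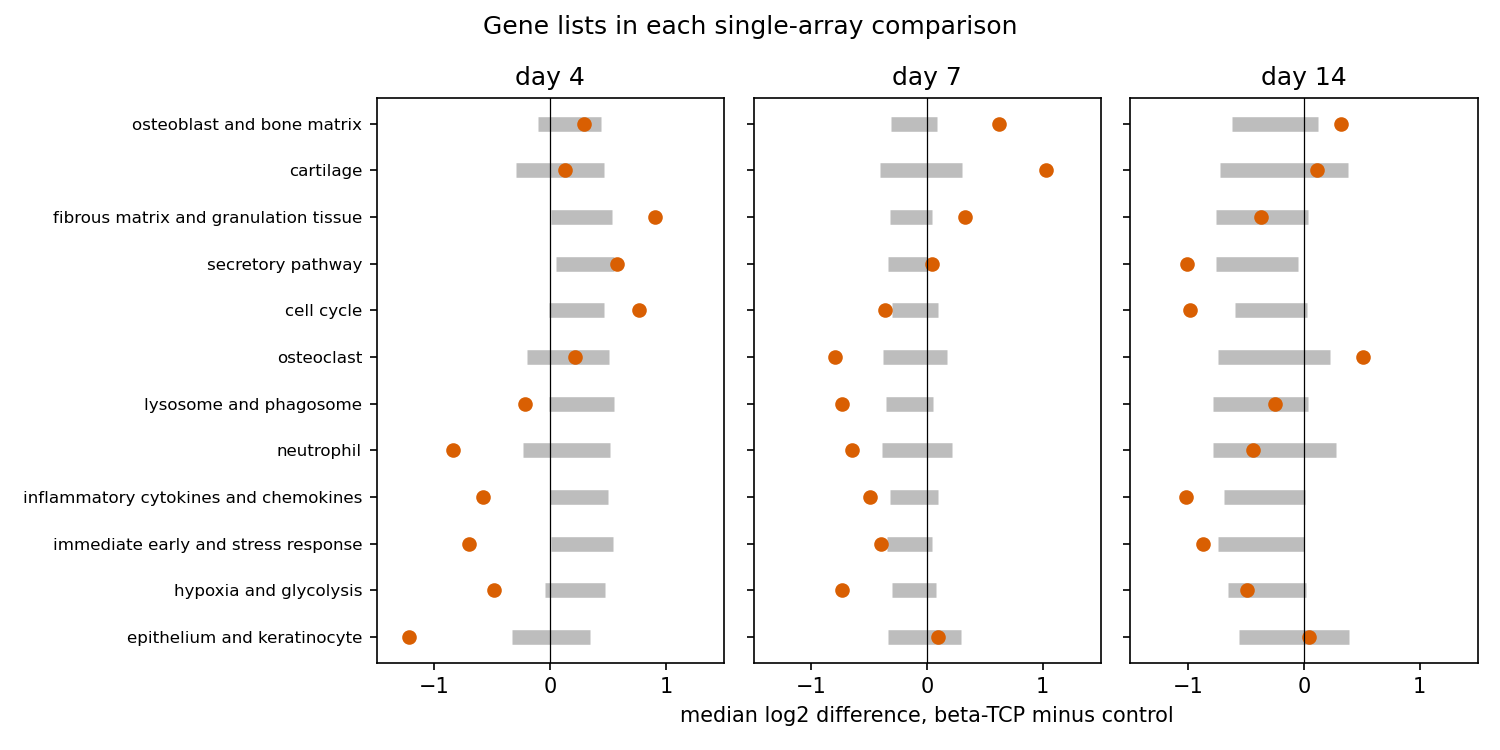
Median log2 difference, beta-TCP minus control, of 12 gene lists on each day (points), with the band of medians of random expression-matched lists (grey bars). The inflammatory list lies below its bar on all 3 days (-0.58, -0.49 and -1.02), and the osteoclast list below it at day 7 and above it at day 14.

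The next question was which differences the 3 days shared. Across genes, which are not independent replicates, the differences correlated at r = 0.226 between days 4 and 7, at -0.075 between days 4 and 14 and at -0.076 between days 7 and 14. Between days 4 and 7, 72 genes were at least 2-fold higher on both, against 14.1 for independent lists, and 69 lower on both, against 11.2. Another 17 differed at least 2-fold in opposite directions. For days 4 and 14 these were 15 higher (against 16.6), 92 lower (against 50.3) and 147 opposite. For days 7 and 14 they were 27 higher (against 10.9), 79 lower (against 55.8) and 123 opposite. Numbers for independent lists were not calculated for opposite directions. In both pairs with day 14, opposite genes outnumbered those lower on both days (147 against 92, and 123 against 79). The excess of lower genes over independent lists therefore does not show by itself that day 4 or 7 shared differences with day 14. On all 3 days 4 genes were at least 2-fold higher, CDH2, COL9A1, IBSP and the BMP target ID1, against 0.490 for independent lists. On all 3 days 40 genes were lower, against 1.73, among them the decoy receptor gene IL1R2, the platelet chemokine gene PPBP, CCL3, PTGS2, tissue factor (F3), SLC2A1, ADM and TREM1.

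**Figure D3:**
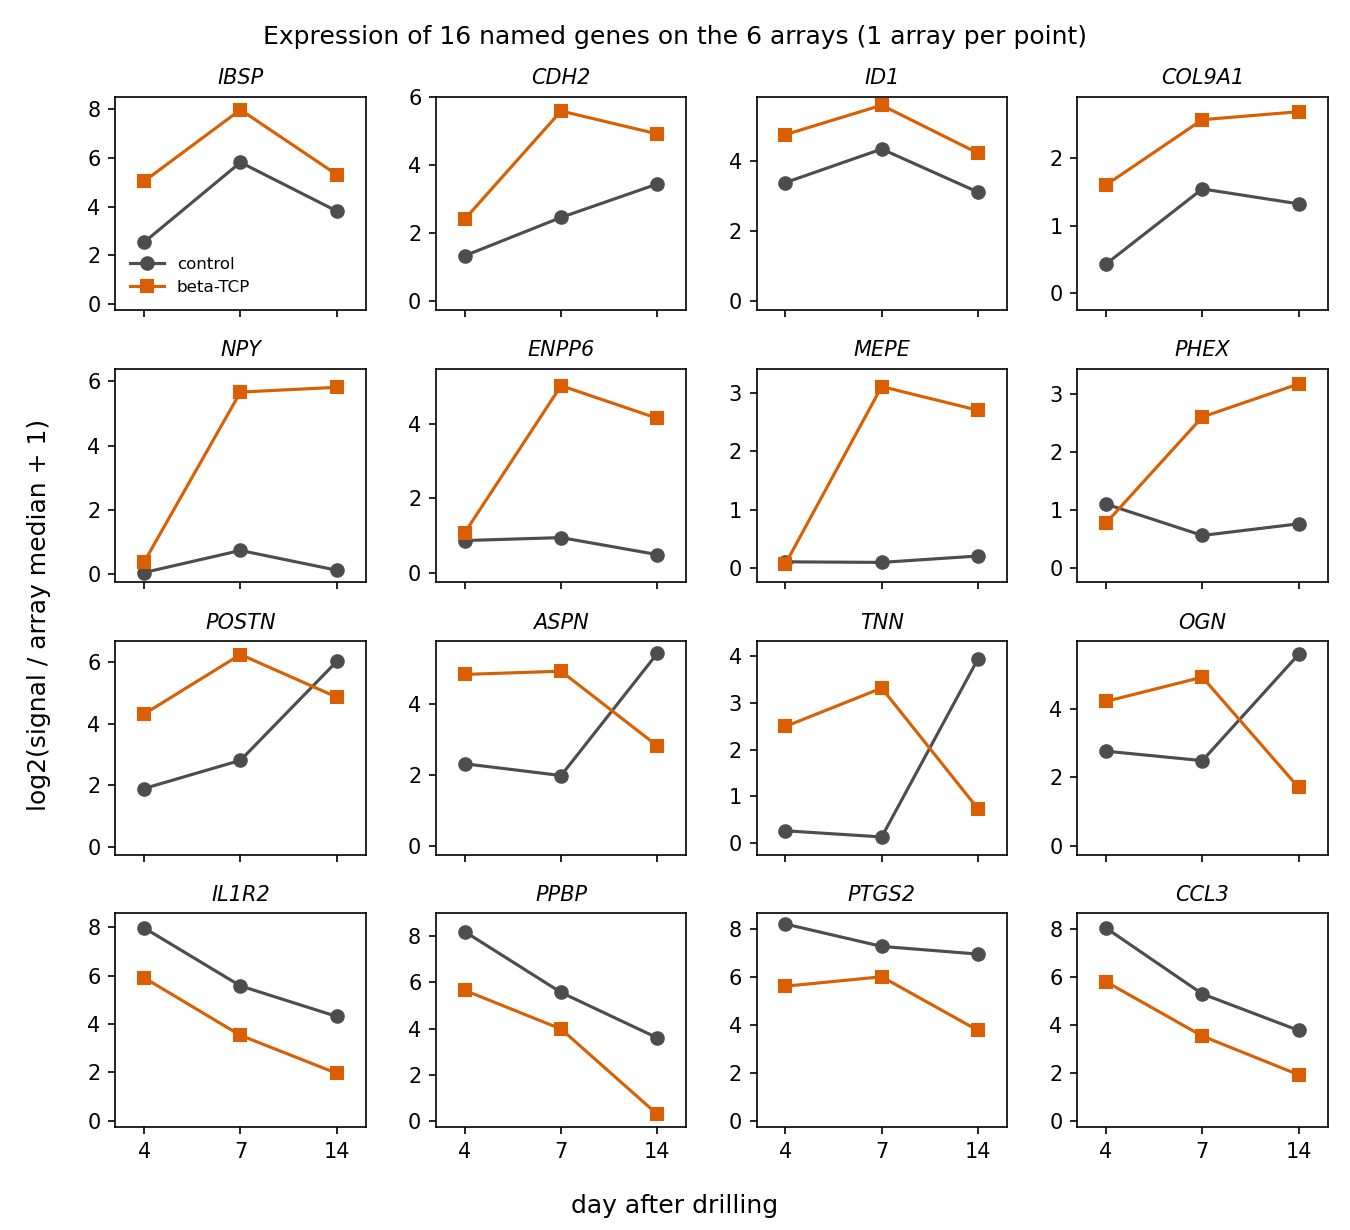
Log2 of signal over the array median plus 1 for 16 named genes by day, control (grey circles) and beta-TCP (orange squares), 1 array per point, joined by lines. IBSP, CDH2, ID1 and COL9A1 are higher with beta-TCP on all 3 days, and IL1R2, PPBP, PTGS2 and CCL3 are lower. POSTN, ASPN, TNN and OGN are higher at days 4 and 7 and lower at day 14. POSTN, TNN and OGN were read on CfaAffx probe sets and ASPN on a Cfa probe set.

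Averaged over the 3 days in limma's additive fit, no gene passed an adjusted p of 0.05 (0 of 10550, 0 higher and 0 lower). The lowest adjusted p was 0.158, and 513 of the 10550 genes had an unadjusted p under 0.05 (141 higher, 372 lower). That is no more than this threshold would give with no effect on any gene. The genes with the smallest p that had the same sign on all 3 days were IL1R2 (-2.15 ± 0.30, SE), PPBP (-2.48 ± 0.37), CCL3 (-1.95 ± 0.31) and IBSP (2.05 ± 0.33). PTGS2, ZFP36, GK, F3, ISG20, DGAT2 and AREG followed on the lower side, between -2.35 and -1.64. SAMD11, NPY, CDH2, ENPP6, MAB21L2, APOD, KCNK2, ID1 and COL9A1 followed on the higher side, between 1.19 and 3.64. Other probe sets of the genes named from this fit were not compared individually in it. Adjusted over each list alone, uncorrected for the number of lists, 8 of 24 inflammatory genes and 6 of 22 immediate early genes passed. So did 4 of 11 neutrophil genes, 4 of 26 hypoxia genes and 2 of 22 osteoblast genes (IBSP and MEPE). Other lists had at most 1 such gene, and no member of any list passed over all genes. MEPE read only 0.09 to 0.20 on the control arrays and 0.07 on the beta-TCP day 4 array.

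That 0 depends on which days enter. Without the day 4, day 7 or day 14 pair, 14, 29 and 227 genes passed, each with 1 residual degree of freedom. In the fit without day 14, whose genes were looked at only after this count was known, 113 genes were higher and 114 lower. The higher ones included POSTN (2.93 ± 0.35, SE), PTN (2.74 ± 0.35), ASPN (2.74 ± 0.34), IBSP, the Wnt antagonist gene SFRP2, ALPL, PTH1R and ACAN. The lowest were SERPINB2 (-2.26) and KRTDAP (-2.07), and the lower ones also included PPBP, IL1R2, CCL3, PTGS2, IL1B, SLC2A1, OSM, LTF and the further epithelial genes S100A14, S100A2, IVL and SBSN. KRTDAP differed by -3.82 at day 4 and by -0.31 at day 7. Of the 113, 30 were also higher at day 14, and of the 114, 89 were also lower, where of all genes 36.9% were higher and 63.1% lower. Relative to the median of all genes at day 14, 40 of the 113 were higher and 83 of the 114 lower. The prior of that fit carried 213.7 degrees of freedom, so nearly the same SE applied to every gene.

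By camera with the preset correlation, 12 of the 30 lists passed for the average beta-TCP effect, 6 higher and 6 lower. No list passed with an estimated correlation (lowest adjusted p = 0.333 with an estimated correlation) or by fry (lowest adjusted p = 0.193). At the preset correlation, inflammatory genes (median -0.80, 23 of 24 lower), hypoxia and glycolysis genes (-0.52, 26 of 26 lower), immediate early genes (-0.55) and neutrophil genes (-0.50) were lower. So were lysosome genes (-0.27) and antigen presentation genes (-0.33, 20 of 20 in the average over days). By single days the antigen presentation list left the band only at day 14 (-0.86), and its highest median was 0.12. Osteoblast genes (0.30), cartilage genes (0.45), fibrous matrix genes (0.22), smooth muscle and pericyte genes (0.21), Wnt pathway genes (0.07) and BMP and TGF-beta pathway genes (0.12) were higher.

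The last question was how expression differed between days, with day 14 deposited on another scale than days 4 and 7. On both day 14 arrays the sibling probe sets left out also ran the other way round, so day 14 and its processing cannot be told apart in any difference from day 4 or 7. Between days 4 and 14, 2789 genes differed at least 2-fold on the control arrays (1964 higher, 825 lower) and 2920 on the beta-TCP arrays (1023 higher, 1897 lower). The median of all genes moved by 0.27 on the control arrays, and relative to it 1167 were higher and 1261 lower. On the beta-TCP arrays it moved by -0.09, and relative to it 1243 were higher and 1663 lower. With quantile normalization the splits were 1258 and 1037, and 1648 and 1508. On the control arrays 25.5% of genes were higher and 7.11% lower with Cfa probe sets alone, against 8.94% and 10.4% with CfaAffx, so the direction of the majority turns with the type of probe set. On the beta-TCP arrays 13.1% were higher and 15.0% lower with Cfa, against 4.14% and 30.5% with CfaAffx. Across genes the changes of both treatments correlated at r = 0.480, with 488 genes higher in both and 497 lower in both, against 190 and 148 for independent lists. A difference in processing shared by both day 14 arrays would enter these counts too.

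Inflammatory genes were lower at day 14 than at day 4 on the control arrays (median -0.50, percentile 0.01) and the beta-TCP arrays (-1.60, percentile 0). With CfaAffx probe sets alone the control arrays gave a percentile of 56.4. Epithelial markers lay at -0.94 on the control arrays (percentile 0) and at 0.17 on the beta-TCP arrays. In the additive fit IL1B differed by -4.50, CCL3 by -4.08, TREM1 by -4.23, PPBP by -4.98 and SOD2 by -4.81, with adjusted p = 0.00101 for IL1B and 0.000579 for the others (limma). SRGN, GK, CCRL2, SERPINA1 and ADGRE3 were the other lowest genes. Of 24 inflammatory genes 10 passed over all genes and 15 adjusted over the list alone, and of 11 neutrophil genes 6 and 8. The highest were complement genes C1S (4.64, adjusted p = 0.000883, limma) and C1R (3.11), the antiangiogenic gene SERPINF1 (3.33), the smooth muscle gene TAGLN (3.22), FBLN1 (3.15), VCAM1 (3.12), von Willebrand factor (VWF, 3.04), RARRES1, FOLH1B and EFEMP2. These 10 highest genes were all read on Cfa probe sets, and 6 of the 10 lowest on CfaAffx. Other probe sets of these highest and lowest genes were not compared individually for this difference. Within genes measured on both types, CfaAffx minus Cfa moved by a median of -0.52 on the control arrays and -1.19 on the beta-TCP arrays between these days. ALPL, the alkaline phosphatase of mineralizing osteoblasts, rose by 2.63 (adjusted p = 0.0119, limma).

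The F test over days called 312 genes, and 518 passed for day 14 minus day 4 (199 higher, 319 lower), 50 for day 7 minus day 4 and 0 for day 14 minus day 7. The 0 between days 14 and 7 stands beside 1026 genes at an unadjusted p under 0.05 in limma. The F test count was 0 with no expression filter and 0 with a pseudocount of 16 or 64, 9 with CfaAffx probe sets alone, 19 with the mean of a gene's probe sets and 96 with a pseudocount of 0.25. It was 1731 without the day 14 beta-TCP array, and 83, 708 and 1105 without the pair of day 4, 7 and 14. By camera 11 of 30 lists passed for day 14 minus day 4 at the preset correlation. None (0) passed with an estimated correlation (lowest adjusted p = 0.678 with an estimated correlation) or by fry (lowest adjusted p = 0.167). At the preset correlation the lists of osteoblasts, fibrous matrix, the Wnt pathway, oxidative phosphorylation and ribosomal proteins were higher. Inflammatory, neutrophil, cell cycle, antigen presentation, hypoxia and immediate early genes were lower. These are averages over both treatments, which did not change alike in every list. In the cell cycle list, beta-TCP minus control had a median of 0.77 at day 4 and -0.99 at day 14.

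The fixed bone and osteoclast markers varied by day. ALPL differed by 1.39, 1.88 and -0.01 at days 4, 7 and 14, with the other probe set at 0.014 on day 4 and -0.71 on day 14, and BGLAP by -0.60, 1.85 and 1.72. SPP1 was between -0.20 and 0.25 on the probe set used, with the other at -0.32, 0.004 and 1.14. COL1A1 lay at -0.02, 0.10 and 0.99, with other probe sets reaching 1.65, 1.79 and -1.36. Each had probe sets of both signs on at least 2 days. CTSK lay at 0.43, -0.51 and 0.69, and CD68 at -0.55, -1.17 and 1.59. At day 14 the second probe set of CTSK lay at -1.20 and that of CD68 at 0.10. TNFSF11, the osteoclast differentiation ligand RANKL, lay at 0.64, -1.09 and -0.68, its decoy receptor gene TNFRSF11B at -0.49, 0.76 and -0.34, and TNFRSF11A at 0.21, 0.49 and -0.02. CD163 lay at -0.29, -0.40 and -2.03. RUNX2, the master transcription factor of osteoblasts, is listed under 2 gene IDs, with differences of 0.07, 0.60 and 0.30 for RUNX2_449531 and of -0.07, 0.15 and -0.34 for RUNX2_474923. CALCR, SOX9, COL2A1 and COL10A1 were below the expression filter, and SP7 was not measured by a probe set assigned to 1 gene.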

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

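Each difference here between days is untested, since 1 array stands behind every group. The tests of explanations and the count of splits were chosen after the result was seen, except the test on a second list of epithelial genes.

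Lists and genes are given here because the sign of beta-TCP minus control differed between days. The osteoclast list had a median of -0.80 at day 7 and 0.51 at day 14. The cell cycle list lay at 0.77, -0.37 and -0.99 on days 4, 7 and 14, and the secretory pathway list at 0.57, 0.045 and -1.01.

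ASPN lay at 2.52, 2.95 and -2.62, POSTN at 2.42, 3.44 and -1.16, TNN at 2.24, 3.19 and -3.21, OGN at 1.45, 2.43 and -3.87, and SERPINH1 at 1.21, 1.08 and -4.06. Of these genes, POSTN, TNN and OGN were read on CfaAffx probe sets, ASPN and SERPINH1 on Cfa. Within 1638 genes measured on both types, the median difference at day 14 was -0.91 on CfaAffx and -0.34 on Cfa. The share of probe set type in these changes of sign was not tested. LPL was 2.39 at day 4 and -1.08 at day 14. The interferon-induced gene MX1 lay at -1.28, 2.04 and -3.43.

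Genes in the opposite order were LAMA3 (-3.67 at day 4, 1.39 at day 7), DSC2 (-2.86 and 1.28 on the same days) and S100A2 (-3.13 at day 4, 1.06 at day 14). CRYAB (-2.41 and 1.90), PKIA (-2.33 and 1.96) and CRYM (-1.08 and 2.48) went from lower at day 7 to higher at day 14.

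The first pattern weighed is the 1627 genes at least 2-fold lower with beta-TCP at day 14. Against probe set type as the whole cause, 13.7% of genes were still lower with Cfa probe sets alone, against 2.69% at day 4. Counting both directions, 1816 genes differed at least 2-fold with arrays scaled to the 90th percentile, against 606 at day 7. This argues against scaling as the cause of the number of genes that differed. The lower genes alone went from 1627 to 848 with that scaling. Scaling remains a candidate explanation of part of the number of lower genes and of the direction, since 53.3% of the 1816 were higher. A loss that depends on probe set type remains one of part of the pattern, with a median CfaAffx minus Cfa of -0.59 within genes. An effect of beta-TCP itself cannot be told apart from the state of this specimen with 1 array.

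The second pattern is the epithelial genes on the control day 4 array. Of 26 further epithelial genes written down before their values were seen, 7 of 12 kept were highest on that array (58.3%). At least 50% had been set beforehand, and of all genes 15.7% were highest there. A first count of 5 of 10 had missed MARVELD3, listed under 2 gene IDs. Both IDs are now counted, among the 12 and among the 7. Oral epithelium in that specimen remains a candidate explanation, and in the first list KRT16 lay at 3.47 against 2.09 on the beta-TCP day 4 array and EPCAM at 3.37 against 0.91. Below the filter 4 of 12 genes of the second list were highest there, and with them the share of that list falls under 50%. Neither JUP (3.13) and PRSS8 (2.96), with high signal on every array, nor CDH1 (0.34) and KRT1 (0.079), near the floor, decide on this explanation. ITGB4, also not highest on the control day 4 array, read 2.80 there and 3.77 on the beta-TCP day 14 array. The 2 IDs of MARVELD3, counted among the 7, read only 1.30 and 1.34 on the control day 4 array. The first list had a median of -1.22 at day 4, with an SD of 0.93 over its genes, and of 0.093 at day 7. That cannot decide whether epithelial genes are lower with beta-TCP on every day. Most genes of the list had little signal left to lose on the control day 7 array (EPCAM 0.85, KRT16 0.64), though PERP lay at 2.13.

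The third pattern is the sibling probe sets that were left out. Of 19 pairs ending in _a_at and _at that lay over 2 log2 units apart at days 4 and 7, 19 matched better on each day 14 array when their names were exchanged, and between control days 7 and 4, 0 of 21 did. Different transcripts in use at day 14 are argued against by pairs ending in _s_at and _at, of which at most 4.26% matched better exchanged. For example, the NDUFC1 probe sets read 7.80 and 0.66 on the control day 4 array and 0.10 and 8.45 on the control day 14 array. An exchange of names is the candidate explanation that remains, and which days carry the right names is open.

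For the average beta-TCP effect, the 6 arrays make only 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 0 genes and the highest other gave 4; that 10 of the 10 splits gave as many follows from the 0.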

How the results depend on the processing

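The alternatives with a pseudocount of 0.25, arrays scaled to the 2% trimmed mean or the 90th percentile, 1 probe set type, sibling pairs kept or exchanged, and without the day 14 beta-TCP array were chosen after seeing the data. Over 15 alternatives the correlation of the differences at days 4 and 7 stayed between 0.185 and 0.298, and those with day 14 stayed below 0 (-0.191 to -0.015 for day 4, -0.118 to -0.050 for day 7). Of the values of single genes under the alternatives, 1958 stayed within the typical spread and 412 moved. A further 8, at least 2-fold different in the main setting, changed sign. Of list percentiles, 2090 stayed inside or outside the band as in the main setting, 125 left the band and 81 entered it. The other 9 lay outside it and crossed past the middle of the random lists. Unless the construction of an alternative shows it, the cause was not tested. Values as deposited were not run between days, since day 14 is on another scale.

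Counts of genes at least 2-fold different are given for beta-TCP minus control at days 4, 7 and 14, then control and beta-TCP arrays over time. The main values are 802, 674, 1994, 2789 and 2920. They became 111, 120, 278, 720 and 507 with a pseudocount of 16, and 22, 23, 62, 208 and 131 with 64, which shrinks differences by construction. At least 1.5-fold they were 3211, 2310, 4505, 5235 and 5497, and at least 3-fold 112, 163, 523, 980 and 1064. A pseudocount of 0.25 gave 1611, 1300 and 3140 on days 4, 7 and 14. Values as deposited gave 6383 at day 14. The mean of the gene's probe sets gave 500 and 393 on days 4 and 7 and 1674 on the control arrays over time. Cfa probe sets alone gave 473, 404 and 1040 on days 4, 7 and 14 and 1687 on the beta-TCP arrays over time, and CfaAffx probe sets alone gave 445 at day 7 and 1607 on the control arrays over time, with fewer genes tested.

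The day effect of 312 genes became 0 with no filter, 0 with a pseudocount of 16 or 64, 96 with 0.25, 19 with the mean of probe sets, 473 with the trimmed mean, 9 with CfaAffx probe sets alone, 1731 without the day 14 beta-TCP array, and 83 to 1105 when a day's pair was left out (83, 708 and 1105 without days 4, 7 and 14). The beta-TCP effect over days, 0 genes, became 3 with Cfa probe sets alone and 14 to 227 when a day's pair was left out (14, 29 and 227). With an estimated correlation, camera's 12 lists for beta-TCP and 11 for day 14 minus day 4 became 0 and 0. Of the lists outside the band for beta-TCP day 14 minus day 4, 10 became 6 with a pseudocount of 16. With CfaAffx probe sets alone, the correlation of days 4 and 14 moved from -0.075 to -0.191.

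With CfaAffx probe sets alone, percentiles that crossed to the other side were those of osteoclast (49.96), inflammatory (63.85) and smooth muscle genes (8.03) at day 14, metalloproteinases at day 7 (68.43), inflammatory genes on the control arrays over time (56.41) and smooth muscle genes on the beta-TCP arrays over time (43.99). Metalloproteinases at day 7 also crossed without _x_at and _s_at probe sets (83.85), smooth muscle genes at day 14 with the mean of probe sets (20.34), and coupling factors at day 4 with no filter (48.01). Changes of sign are listed only for genes at least 2-fold different in the main setting. ACP5 changed sign with CfaAffx probe sets alone (-0.84 at day 14, -0.69 over time with beta-TCP). Over time with beta-TCP, so did CTSK (-2.89 with CfaAffx, -0.86 with the mean) and CD68 (-1.22 with CfaAffx). MSN did with Cfa alone (-0.67 at day 14). SPP1 did over time with beta-TCP (0.51 with Cfa alone and 0.51 without _x_at and _s_at probe sets). No paired analysis was possible by replicate number because each group holds 1 array; the fit with day as a term compares the 3 pairs of arrays that share a day.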

Other observations

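The tests of healing time in this part were chosen after the result was seen.

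On single arrays, endothelial genes were higher at day 14 than at day 4 on the control arrays (median 1.16, percentile 100, 13 of 23 at least 2-fold) and on the beta-TCP arrays (0.42, percentile 98.8), led by VWF (3.38 and 2.71). In the additive fit this list did not pass for day 14 minus day 4 (camera in limma, adjusted p = 0.105 at the preset correlation; fry, 0.495), nor did smooth muscle and pericyte genes (0.0520 and 0.168). Smooth muscle and pericyte genes lay at 0.89 and 0.68, with ACTG2 at 2.25 and 2.51; with CfaAffx probe sets alone the percentile on the beta-TCP arrays went from 99.3 to 43.99. The fibrous matrix list had a median of 1.73 on the control arrays (16 of 23 genes at least 2-fold) and lay at 0.26 on the beta-TCP arrays, inside the band (percentile 86.8). All 26 secretory pathway genes were higher on the control arrays (median 1.29), against 7 of 26 on the beta-TCP arrays (-0.40), and the difference between treatments was not tested.

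The macrophage list lay below the band at day 4 (median -0.22, percentile 0.11). Its genes were split there, 12 higher and 13 lower, with 2 at least 2-fold higher and 0 lower. The list lay inside the band at day 7 (percentile 25.2) and day 14 (-0.67, percentile 3.14, 19 of 25 lower). At day 7 GPNMB (2.54) and VSIG4 (1.69) were higher with beta-TCP and MARCO (-1.79) and CD68 (-1.17) lower, with a list median of -0.19. At day 14 MARCO (-3.39), GPNMB (-3.20) and CD163 (-2.03) were lower. Interferon genes varied by day, with ISG15 at -1.78 on day 4 and -2.78 on day 14, and IFI44 at 1.12 on day 7. Of 30 lists, 9 stayed inside the band on all 3 days, those of adipocytes, B cells, T cells, skeletal muscle, nerve, calcium handling, oxidative phosphorylation, ribosomal proteins and reference genes. Erythroid genes left it upwards at day 14 (0.42, percentile 98.1), coupling and growth factor genes at day 4 (0.48, percentile 99.1), and matrix metalloproteinases downwards at day 7 (-0.41, percentile 1.43). The percentile of coupling genes was 48.0 with no filter, and that of metalloproteinases 68.4 with CfaAffx probe sets alone.

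One hypothesis is that beta-TCP sites may have been ahead of control sites in healing time. Across genes, the difference at day 4 correlated at r = 0.223 with control day 14 minus day 7, and the difference at day 7 at r = 0.235 with control day 14 minus day 4, pairs that share no array. With Cfa probe sets alone these were 0.249 and 0.213. On the beta-TCP arrays, the difference at day 4 correlated at -0.0399 with day 14 minus day 7, and at 0.0296 with Cfa probe sets alone, so that test decides nothing. Genes are not independent replicates, and the hypothesis stays open.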
